A study of Mus musculus with 34 samples.

How the data were processed

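Gene expression was measured by RNA sequencing in the hippocampus of 34 mice of 6 months of age. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was enriched, strand-specific libraries were made and read as pairs of 150 bp on a NovaSeq instrument. The animals carried 1 of 4 genotypes and received either 15 mg/kg tofacitinib or vehicle (0.5% methylcellulose, here called sham) by oral gavage every day for a month. Groups, replicate numbers and sex were taken from the sample labels.

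The deposited table of counts held whole, unnormalised read counts per gene for each library, and the submitters' processing notes name bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5, HTSeq 0.6.1 and the build GRCm38 without giving their roles. The deposited RPKM table, made by the authors, gave RPKM (reads per kilobase of gene and M reads) for the same libraries. For 12463 genes with at least 20 counts, the RPKM values equalled the counts divided by the library's sum of counts and a length per gene, to a relative deviation of 7.77e-16, and they were not tested again. Gene models were those of GENCODE mouse release 24, going by the names of the deposited files, on GRCm38. The strand setting used in counting was not given in the sources used here, so overlapping and antisense genes may share reads. How reads that match several copies of a gene were counted was not given either, and paralogs such as the Ifit and Oas genes, the H2 class I genes and the histone genes are uncertain for that reason. Chromosome positions are from the annotation given for this work (GENCODE release 21 of the same build), which held 55144 of the 55385 gene identifiers (99.6%), all on the same chromosome.

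Library totals ranged from 14.9 to 21.1 M counts (median 17.8 M). Counts were scaled with TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, R 4.3.3) after filterByExpr by group, which left 17518 genes. All 34 libraries entered 1 fit with a mean for each of the 8 groups and a term for sex, leaving 25 residual degrees of freedom, with a median prior of 5.84. Comparisons were contrasts of that fit, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Unless another tool is named, every adjusted p of a gene is from this test. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. Levels per group are CPM (counts per M counts of the library in the genes that passed the filter, scaled with TMM) as mean ± SD. The labels number the animals of a group and do not say that equal numbers share a litter or day, so no pairing entered the fit.

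For Dp16 the genes of chromosome 16 from the start of Lipi to the end of Zbtb21 (75540514 to 97962622, 22.4 Mb, GRCm38) were taken as the triplicated segment. Of its 384 genes in the files, 107 passed the filter. For each animal the mean log2 CPM of the segment was compared between groups with an exact two-sided permutation test of animals.

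A total of 37 gene lists for cell types, brain regions, interferon and JAK-STAT signalling and other pathways were fixed, and 35 of them were tested as sets. Of 665 listed entries 663 matched a gene in the files. Genes of the segment and genes tied to the transgenes were left out of the other lists in set tests. Sets were tested with camera (limma 3.58.1) with a preset correlation of 0.01, two-sided, adjusted over the 35 lists of a comparison. An inter-gene correlation estimated for each list and fry were run beside it. Beside the members past the threshold over all genes, the number past it when adjusted over the list alone is given. List levels of an animal are mean log2 CPM with a prior count of 2. These were compared by exact two-sided permutation of animals, and for the mean over genotypes by 100000 permutations within genotypes. Permutations of list and segment levels did not take sex into account.

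The genes named were chosen by a rule. It takes 10 check genes, among them App, Thy1, Ifnar1, Ifnar2, Ifngr2, Il10rb, Gfap and Cst7, and some genes the rule selects are not reported here. To these it adds the 10 largest rises and 10 largest falls past the threshold with at least 1 CPM, for Dp16 inside and outside the segment. It also adds up to 4 members with the smallest p from each list whose set test passed or that had 2 members past the threshold, and, where fewer than 5 genes passed, the 5 smallest p. Gene models with no name of their own were counted and not named. The groups, comparisons, tests, lists, this rule and the other settings named next were fixed before the data were examined.

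Alternatives were DESeq2 size factors in the edgeR fit, no filter on low counts, no sex term, the replicate number as a block, 2 surrogate variables (sva 3.50.0), a fit on the libraries of the compared groups alone, DESeq2 1.42.0, the estimated correlation, and leaving out each library in turn. A fit without 3 libraries low in hippocampal markers and the permutation test of list levels were added after the data were seen. Each library's total, its hippocampal marker level and its levels of markers of other regions and tissues were examined. Other splits of the compared libraries were drawn up to 100 times for each comparison. Analyses in Python 3.11.15 used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

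The gene test was tested on simulated counts for the same libraries in which 200 of 17518 genes were changed. For Dp16 against WT sham animals, 14 of 66 genes changed 1.5-fold were called, 32 of 67 changed 2-fold and 44 of 66 changed 4-fold, with 2 of 17062 unchanged genes called. For tofacitinib averaged over the 4 genotypes, 42 of 65, 54 of 65 and 63 of 66 were called, with 5 of 17060 unchanged genes called. In a simulated list of 30 genes shifted by 0.5 on the log2 scale, camera gave an adjusted p of 1.4e-28 with the preset and 9.68e-11 with an estimated correlation, and 0 of 49 unshifted lists were called either way. The simulated genes varied independently and the lists were drawn at random. This check therefore cannot tell whether the preset gives false calls for lists of correlated genes. With 3 to 5 animals per group, many 1.5-fold changes were below what the test could call.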

Results

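RNA was sequenced from the hippocampus of 34 mice of 6 months of age. Wild-type mice (WT), Dp16 mice, 5xFAD mice and mice carrying both (5xFAD-Dp16) received sham gavage or tofacitinib, an oral inhibitor of Janus kinases (JAK), for a month. Dp16 mice carry an extra copy of the segment of mouse chromosome 16 that matches human chromosome 21 and serve as a model of Down syndrome. 5xFAD mice carry human transgenes with mutations of familial Alzheimer's disease and develop amyloid plaques. Sham groups held 5 WT, 3 Dp16, 4 5xFAD and 3 5xFAD-Dp16 animals, and tofacitinib groups held 5 WT, 5 Dp16, 5 5xFAD and 4 5xFAD-Dp16 animals (16 female and 18 male in all). Females were 2 of the WT, 2 of the Dp16, 1 of the 5xFAD and 2 of the 5xFAD-Dp16 sham animals. With tofacitinib there were 2 females in WT, 3 in Dp16, 2 in 5xFAD and 2 in 5xFAD-Dp16. Library 4 was the only male of the 5xFAD-Dp16 sham group. The design text names 6 tofacitinib 5xFAD and 4 sham 5xFAD-Dp16 animals, of which 1 each has no library among the 34 samples of the series. Libraries held 16.4 to 21.1 M counts in WT sham, 17.0 to 18.7 in Dp16 sham, 17.5 to 20.3 in 5xFAD sham and 15.8 to 19.7 in 5xFAD-Dp16 sham libraries. In the tofacitinib groups they were 14.9 to 19.3 M in WT, 17.0 to 20.4 in Dp16, 16.4 to 18.9 in 5xFAD and 17.5 to 21.0 in 5xFAD-Dp16 libraries. The tests covered 17518 genes. Libraries are separate animals by their numbers in the labels.

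The genes that mark the labels followed them. Between female and male animals 11 genes differed, led by Xist and by the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y. Thy1 (chromosome 9, 44043384 to 44048579), whose promoter drives the 5xFAD transgenes, was at 2490 ± 386 CPM in 5xFAD sham (n = 4) and 876 ± 40.2 CPM in WT sham animals (n = 5). Every animal labelled 5xFAD or 5xFAD-Dp16 lay at 967 CPM or more, and no other above 934 CPM. How reads from the transgenes were counted is not given in the sources used here, so the Thy1 and App values of animals with the transgenes are not shown to be levels of the mouse genes alone. App (1630 ± 140 against 1670 ± 207 CPM) did not pass the test between 5xFAD and WT sham animals, with a log2 fold change of -0.02 (adjusted p = 1.0).

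Markers of hippocampal neurons were low in 3 libraries. The mean log2 CPM of the dentate gyrus, CA1 and CA3 lists had a median of 5.57 over all libraries and was 4.52 in WT tofacitinib library 3, 4.17 in 5xFAD tofacitinib library 2 and 4.02 in 5xFAD-Dp16 sham library 4. The thalamus and habenula list, with a median of 3.23, stood at 6.73 in the 5xFAD tofacitinib library and 5.66 in the 5xFAD-Dp16 sham library, where the thalamic transcription factor Tcf7l2 reached 206 and 230 CPM. The neocortex list stood at 5.17 in the WT tofacitinib library, and the highest of the 31 others was at 4.71. The striatum list stood at 5.93 in the WT and 6.66 in the 5xFAD tofacitinib library, against 4.64 in the highest of the others.

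**Figure D1:**
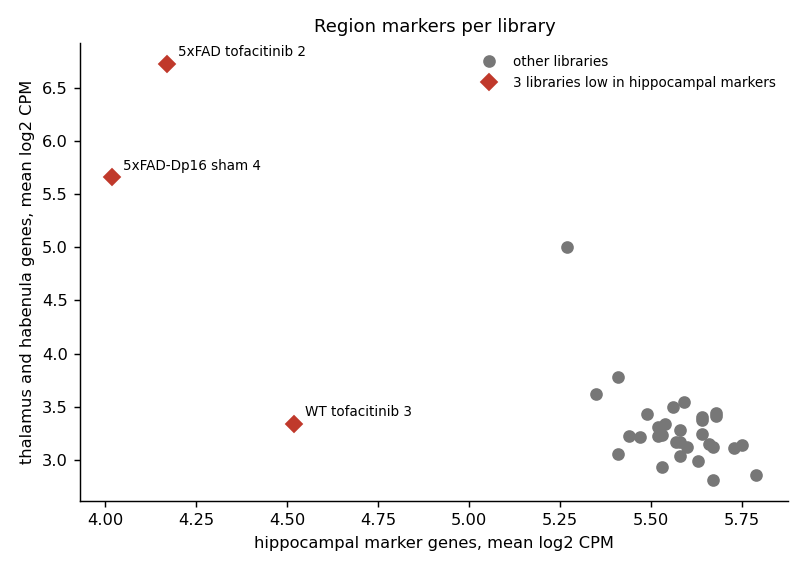
Mean log2 CPM of hippocampal marker genes (x axis; dentate gyrus, CA1 and CA3 lists) and of thalamus and habenula genes (y axis) in each of the 34 libraries. Red diamonds are the 3 libraries low in hippocampal markers, at 4.02 to 4.52, and grey circles the others. The grey circle at 5 on the y axis is 5xFAD-Dp16 tofacitinib library 1.

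The effect of the duplicated segment alone was asked by comparing Dp16 with WT sham animals. Genes of the segment (chromosome 16, 75540514 to 97962622, GRCm38) were higher as a block, by a median of 0.58 on the log2 scale (1.5-fold, interquartile range 0.41 to 0.72), with 104 of the 107 tested genes above 0. Among them rose the interferon receptor subunits Ifnar1 (0.79, SE 0.09, from 34.2 ± 3.2 to 60 ± 1.5 CPM, adjusted p = 7.35e-06) and Ifnar2 (0.88, SE 0.10, adjusted p = 1.1e-05). Of the segment 34 genes passed the threshold over all genes and 64 when adjusted over the list alone, all higher. The mean level of the segment per animal was 4.85 ± 0.024 log2 CPM in Dp16 (n = 3) and 4.2 ± 0.086 in WT animals (n = 5), an exact permutation p of 0.018 (two-sided), the smallest the design allows. The 425 tested genes of chromosome 16 outside the segment had a median of 0.02, with 1 past the threshold.

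Other segment genes that rose were the junction protein Jam2 (0.91), the transcription factor Gabpa (0.78), the neuronal adhesion molecule Dscam (0.71), the chaperone Dnajc28 (0.72) and D16Ertd472e (0.87). Ifnar1 lies at 91485238 to 91507441, Ifnar2 at 91372783 to 91405589, Jam2 at 84774123 to 84825928, Gabpa at 84834925 to 84863779 and Dscam at 96590840 to 97170752. Pigp (0.90) and C2cd2 (0.96) also rose with all libraries in the fit. Of the other receptor genes of the segment, Il10rb (0.56, adjusted p = 0.191) and Ifngr2 (0.54, adjusted p = 0.346) did not pass, nor did the amyloid precursor gene App (0.46, SE 0.14, adjusted p = 0.29, 2320 ± 209 against 1670 ± 207 CPM). Without the 3 libraries low in hippocampal markers, App (0.45, adjusted p = 0.0467) and Ifngr2 (0.54, adjusted p = 5.44e-05) passed. None of the 3 is in the compared groups, so these passes come from the fit shared with the other groups.

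Outside the segment 20 genes changed in Dp16 sham animals, 9 higher and 11 lower. Cbs, the enzyme that turns homocysteine into cystathionine (chromosome 17, 31608894 to 31637238), fell by 0.87 (SE 0.13, 17.7 ± 2.5 against 33.0 ± 2.99 CPM, adjusted p = 0.000287). The prolyl hydroxylase P4htm fell by 0.55 (adjusted p = 0.000849), Armc6 by 0.53 (adjusted p = 0.00808) and Akap8l by 0.48 (adjusted p = 0.0112). The linker histone H1f2 rose by 0.83 (adjusted p = 0.00808) and mt-Atp8, a mitochondrially encoded subunit of ATP synthase, by 1.25 (36.1 ± 13.3 against 15.5 ± 3.14 CPM, adjusted p = 0.00114). The Dp16 values of mt-Atp8 were 44.7 and 42.7 CPM in libraries 1 and 3 and 20.7 CPM in library 2. In Dp16 animals given tofacitinib its mean was 15.2 ± 4.31 CPM.

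Interferon genes were shifted together in Dp16 sham animals, though few passed singly. In the list of type I interferon-stimulated genes 37 of 40 were above 0, with a median of 0.57, and 0 passed over all genes and 5 when adjusted over the list alone (camera adjusted p = 2.53e-11, and adjusted p = 0.188 with an estimated correlation). The 5 became 0 without WT sham library 1 or 4 or Dp16 sham library 1 (median 0.38 without the last), 1 without WT sham library 5 and 3 without Dp16 sham library 3. Lgals3bp, the member with the smallest adjusted p, was at 1.0 (SE 0.25, adjusted p = 0.0929). The list of interferon-gamma and MHC class I genes had a median of 0.42, with 1 of 35 higher, the GTPase Iigp1 (1.04, adjusted p = 0.0276), and 1 when adjusted over the list alone (adjusted p = 0.188 with an estimated correlation), which was 6 without WT sham library 2, 2 without Dp16 sham library 2 and 0 without Dp16 sham library 3. Per animal, the type I list was at 1.79 ± 0.40 mean log2 CPM in Dp16 and 1.25 ± 0.24 in WT animals, an exact permutation p of 0.018 (two-sided), the smallest possible. Immediate-early genes of neuronal activity (median -0.44, adjusted p = 0.53 with an estimated correlation), circadian clock genes (-0.22, adjusted p = 0.203) and heat shock genes (-0.16, adjusted p = 0.498) were called lower. Mitochondrially encoded (0.33, adjusted p = 0.498), choroid plexus (1.24, adjusted p = 0.606) and ependymal genes (0.97, adjusted p = 0.372) were called higher by camera with the preset correlation, and so were complement (0.2, adjusted p = 0.53; 0.13 without Dp16 sham library 1) and myelin genes (0.16, adjusted p = 0.868). Neocortex genes (-0.21, adjusted p = 0.53) were called lower, and none of these 11 lists was called with an estimated correlation.

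In the edgeR test 54 genes passed between Dp16 and WT sham animals, 43 higher and 11 lower, and 9 of the 28 named among them passed in each refit without 1 library (Ifnar1, Ifnar2, Gabpa, D16Ertd472e, Dnajc28, Jam2, Dscam, Cbs and P4htm). The count was 33 without WT sham library 1 and 24, 23 and 31 without Dp16 sham library 1, 2 or 3, and it was 237 with no filter, 98 with the compared groups alone, 94 with DESeq2 and 119 without the 3 low libraries. Armc6, Akap8l and C2cd2 lost their call without each of Dp16 sham libraries 1, 2 and 3, with highest adjusted p of 0.105, 0.105 and 0.0821 over the refits, and C2cd2 also without WT sham library 1. Pigp lost it without Dp16 sham library 2 or 3 or WT sham library 1 (highest 0.264), H1f2 without Dp16 sham library 1 or 2 (0.0765), mt-Atp8 without Dp16 sham library 1 (0.0532) and Iigp1 without any 1 library but WT sham library 1 (0.346).

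**Figure D2:**
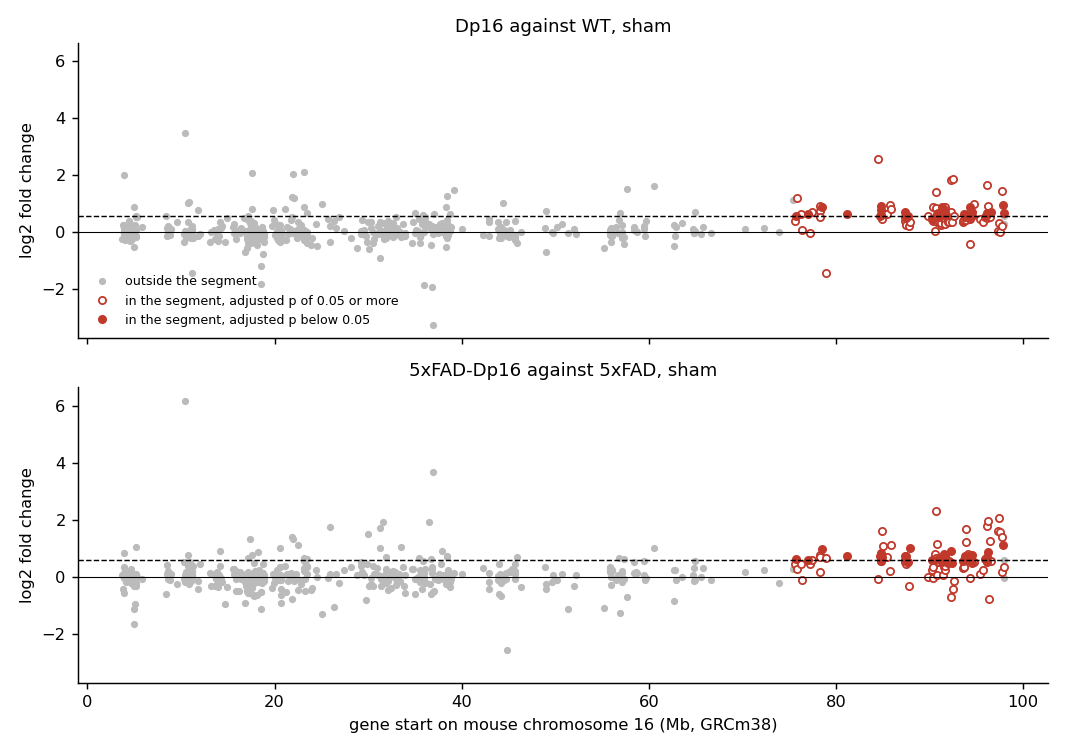
Log2 fold change of each tested gene of chromosome 16 by its start (Mb, GRCm38), for Dp16 against WT (top) and 5xFAD-Dp16 against 5xFAD sham animals (bottom). Grey points lie outside the segment of 75540514 to 97962622. Red circles lie in it, filled where edgeR's adjusted p was below 0.05. The dashed line marks a 1.5-fold higher level, and the segment's median was 0.58 in both.

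The effect of the 5xFAD transgenes alone was read from 5xFAD against WT sham animals. Microglial genes rose. The cystatin Cst7 (chromosome 2, 150570415 to 150578944), a marker of microglia at plaques, stood at 29.2 ± 19.3 CPM (n = 4) against 0.11 ± 0.155 CPM (n = 5; log2 fold change 7.96, SE 0.88, adjusted p = 1.35e-05). The chemokine Ccl6 rose by 2.93 (SE 0.33, adjusted p = 9.84e-06), the lectin receptor Clec7a by 4.19, the receptor Gpr84 by 2.58, the lysosomal glycoprotein Cd68 by 1.79 (45.3 ± 18.9 against 13.1 ± 1.59 CPM) and the protease Ctsd by 1.13 (554 ± 153 against 255 ± 20.7 CPM). The interferon-induced Lgals3bp rose by 1.54 (adjusted p = 0.000618). Thy1 rose by 1.51 (adjusted p = 0.000152). In all 78 genes were higher and 0 lower.

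Of 30 genes of plaque-associated microglia 13 rose and 0 fell (median 1.01, 20 higher when adjusted over the list alone), among them Itgax (4.11) and the chemokine Ccl3 (4.09). Of 16 homeostatic microglia genes 4 rose, among them Olfml3 (0.92), the transcription factor Sall1 (0.56) and the fractalkine receptor Cx3cr1 (0.76), with 12 higher when adjusted over the list alone. Of 14 complement genes 6 rose, including C1qa (1.19), C1qb (1.09) and the receptor C3ar1 (1.63), with 7 when adjusted over the list alone. Of the 40 type I interferon-stimulated genes 1 rose and 20 when adjusted over the list alone (median 0.75), and the 20 became 13, 12, 10 and 9 without WT sham library 1, 4 or 5 or 5xFAD sham library 2. Of 35 interferon-gamma and MHC class I genes 4 rose, such as the transcription factor Irf8 (1.25) and the antigen-presenting molecule H2-D1 (0.86), and 14 when adjusted over the list alone, which became 9, 8 and 8 without WT sham library 4 or 5 or 5xFAD sham library 2. The list of JAK-STAT signal transducers had a median of 0.23 with 0 of 25 past the threshold either way. These 6 lists were called by camera with the preset and with an estimated correlation (adjusted p of 2.26e-05 for plaque-associated microglia, 7.46e-05 for complement, 0.00177 for type I interferon, 0.0088 for homeostatic microglia and for interferon-gamma, and 0.0287 for JAK-STAT transducers). The astrocyte marker Gfap was at 982 ± 312 against 467 ± 74.8 CPM and did not pass (log2 fold change 1.07, adjusted p = 0.503).

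Camera with the preset correlation also called reactive astrocyte genes higher (median 0.25, 1 of 28 past the threshold and 2 when adjusted over the list alone, adjusted p = 0.109 with an estimated correlation). The 1 became 0 without any 1 library but 5xFAD sham library 4, and the 2 became 0 without 5xFAD sham library 2, 1 without WT sham library 1, 2 or 3 or 5xFAD sham library 1 or 3, and 3 without 5xFAD sham library 4. It called cholesterol biosynthesis (0.15, adjusted p = 0.559 with an estimated correlation), choroid plexus (1.34, adjusted p = 0.916) and ependymal genes (0.56, adjusted p = 0.719) higher, and myelin (-0.15, adjusted p = 0.811) and inhibitory neuron genes (-0.11, adjusted p = 0.266) lower. Without the 3 low libraries Gfap passed between these groups (1.06, adjusted p = 0.00261), as did the reactive astrocyte list with an estimated correlation (adjusted p = 0.0403). None of the 3 is in these groups, so these passes come from the fit shared with the other groups.

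Of the named genes, Cst7, Ccl6, Clec7a, Gpr84, Cd68, Ctsd, Thy1 and Lgals3bp passed in each of the 9 refits without 1 library. The count of 78 was 40 without WT sham library 4, 50 without WT sham library 5, 46 without 5xFAD sham library 1 and 12 without 5xFAD sham library 2, and it was 245 with no filter, 129 with 2 surrogate variables, 22 with the replicate number as a block and 14 with the compared groups alone. Itgax, Ccl3, Olfml3, C1qa, C1qb and C3ar1 lost their call without 5xFAD sham library 2 alone (adjusted p from 0.0642 to 0.158). Sall1, Cx3cr1, Irf8 and H2-D1 lost theirs without that library (0.219, 0.254, 0.0811 and 0.177), and Sall1, Cx3cr1 and H2-D1 also without WT sham library 4, Cx3cr1 and H2-D1 without WT sham library 5 and Irf8 without 5xFAD sham library 1. Without 5xFAD sham library 2, 6 plaque-associated, 0 homeostatic, 0 complement and 0 interferon-gamma genes passed. Without 5xFAD sham library 4, 8 homeostatic genes passed, and without WT sham library 4, 2 homeostatic, 3 complement and 1 interferon-gamma genes. Of the interferon-gamma list 1 passed without WT sham library 5 or 5xFAD sham library 1 and 2 without WT sham library 1 or 5xFAD sham library 3.

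In 5xFAD-Dp16 against WT sham animals, which carry both changes, interferon-stimulated genes rose. Ifit1 and Ifit3, antiviral effectors, rose by 2.08 (SE 0.34, from 2.25 ± 0.575 to 9.97 ± 0.888 CPM, adjusted p = 0.000672; n = 3 and 5) and 1.82 (adjusted p = 0.000605), Oasl2 by 2.16 and Lgals3bp by 1.60. The interferon-induced Phf11b (3.78) and Ifi204 (3.64) rose from under 1 CPM. Of the 40 type I interferon-stimulated genes 24 rose and 0 fell, 37 when adjusted over the list alone, with a median of 1.54 (camera adjusted p = 8.89e-05 with an estimated correlation). Per animal the list was at 2.75 ± 0.24 mean log2 CPM in 5xFAD-Dp16 against 1.25 ± 0.24 in WT animals, an exact permutation p of 0.018 (two-sided), the smallest possible, and 0.048 without 5xFAD-Dp16 sham library 4 (n = 2 and 5), again the smallest possible.

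Of the 35 interferon-gamma and MHC class I genes 9 rose, 29 when adjusted over the list alone (median 1.0, adjusted p = 0.00131 with an estimated correlation), and the 29 became 14 without 5xFAD-Dp16 sham library 4. They included H2-K1 (1.00), H2-D1 (1.15), their light chain B2m (0.89) and Iigp1 (1.61). Of plaque-associated microglia genes 4 of 30 rose, 21 when adjusted over the list alone (median 0.73, adjusted p = 0.0164 with an estimated correlation), with Cst7 at 10.2 ± 6.88 CPM (log2 fold change 6.47) and Ccl6 at 1.90. Of 14 complement genes 2 rose, 7 when adjusted over the list alone (median 0.77, adjusted p = 0.0164 with an estimated correlation), and the 7 became 4 without 5xFAD-Dp16 sham library 2. The list of JAK-STAT transducers had a median of 0.29 with 1 of 25 higher and 2 when adjusted over the list alone (adjusted p = 0.0499 with an estimated correlation), a call lost without the 3 low libraries (median 0.15, adjusted p = 0.478). Segment genes rose, 41 of 107, such as Ifnar1 (0.72, adjusted p = 1.33e-05), Ifnar2 (0.85), Il10rb (0.75), App (0.69, 2720 ± 276 CPM), Jam2 (0.92) and the adaptor Samsn1 (1.88). Falls included P4htm (-0.46), the transcription factors Mxd4 (-0.55) and Deaf1 (-0.55), the phagocytic opsonin Mfge8 (-0.83) and the adrenergic receptor Adra2c (-0.84).

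Markers of other regions moved with this comparison. The thalamus and habenula list was higher by a median of 1.16 (adjusted p = 0.558 with an estimated correlation; -0.15 without the 3 low libraries), and myelin genes by 0.57 with 0 of 22 past the threshold and 13 when adjusted over the list alone (adjusted p = 0.405 with an estimated correlation, and a median of 0 without the 3 low libraries). Fibroblast genes were higher by 0.92 (adjusted p = 0.558) and reactive astrocyte genes by 0.45 (adjusted p = 0.271), while excitatory neuron (-0.25, adjusted p = 0.558), CA1 (-0.35, adjusted p = 0.558), neurogenesis (-0.36, adjusted p = 0.288), immediate-early (-0.66, adjusted p = 0.324), clock (-0.22, adjusted p = 0.271) and ribosomal protein genes (-0.25, adjusted p = 0.558) were lower. All 10 were called by camera with the preset correlation and not with an estimated one. Without the 3 low libraries, 5xFAD-Dp16 sham library 4 among them, the medians were 0.13 for fibroblast, 0.12 for reactive astrocyte (0.10 without that library alone), 0.07 for excitatory neuron, 0.09 for CA1, -0.13 for neurogenesis, -0.24 for immediate-early, -0.15 for clock and -0.21 for ribosomal protein genes. The rises of the glycine receptor gene Glra1 (8.09) and of Th, the rate-limiting enzyme of catecholamine synthesis (5.47), rested on 5xFAD-Dp16 sham library 4, where Th was at 75 CPM. Without that library their log2 fold changes were -0.18 (adjusted p = 1.0) and -0.65 (adjusted p = 0.982).

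The edgeR test called 168 genes between 5xFAD-Dp16 and WT sham animals, 143 higher and 25 lower, and 85 without the 3 low libraries, where the type I interferon list held 14 called genes and a median of 1.3 (adjusted p = 0.000205 with an estimated correlation). The count was 1270 with no filter, 348 with DESeq2, 109 with the replicate number as a block and 0 with the compared groups alone, and 91, 97 and 100 without WT sham library 1, 4 or 5 and 415, 474 and 65 without 5xFAD-Dp16 sham library 1, 2 or 4. Ifit1, Ifit3, Oasl2, Lgals3bp, Phf11b, Iigp1, H2-K1, H2-D1, B2m, Cst7, Ccl6, Ifnar1, Ifnar2, Jam2 and Samsn1 passed in each refit without 1 library, Ifi204 did not without WT sham library 1 (adjusted p = 0.0724, the highest of its refits). App (0.149), Il10rb (0.274), P4htm (0.0522), Mxd4 (0.113), Deaf1 (0.0858), Mfge8 (0.204) and Adra2c (0.238) lost their call without 5xFAD-Dp16 sham library 4 alone. Without that library 13 type I and 4 interferon-gamma genes passed. The interferon-gamma count was 4 and 5 without WT sham library 4 or 5, and the plaque-associated count 2 without WT sham library 1 or 4. The complement count was 0 without WT sham library 2 or 5 or 5xFAD-Dp16 sham library 1, and 1 without WT sham library 1 or 4 or 5xFAD-Dp16 sham library 2.

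**Figure D3:**
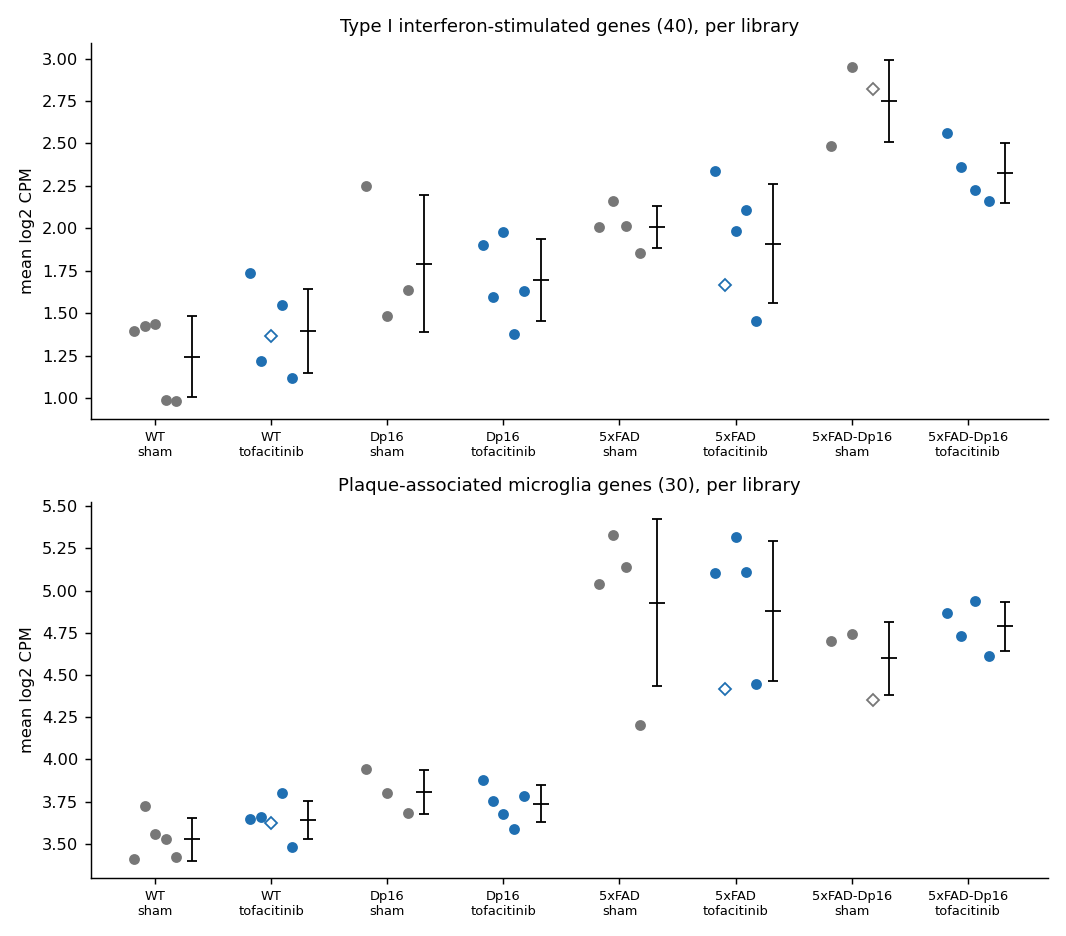
Mean log2 CPM per library of the 40 type I interferon-stimulated genes (top) and the 30 plaque-associated microglia genes (bottom) in the 8 groups, sham in grey and tofacitinib in blue. Each point is 1 animal, open diamonds are the 3 libraries low in hippocampal markers, and bars give mean ± SD. The interferon list averages 1.25 in WT and 2.75 in 5xFAD-Dp16 sham animals.

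The effect of the segment on the 5xFAD background was measured between 5xFAD-Dp16 and 5xFAD sham animals. The segment was higher by a median of 0.58 (1.5-fold), with 33 of 107 genes higher over all genes and 63 when adjusted over the list alone. Its level per animal was 4.8 ± 0.087 against 4.24 ± 0.107 log2 CPM (n = 3 and 4, exact permutation p = 0.029, two-sided, the smallest possible). The membrane protein Tmem50b (0.80, SE 0.07, 129 ± 9.39 against 73.2 ± 7.69 CPM, adjusted p = 8.33e-08), the nuclear ATPase Morc3 (0.75), D16Ertd472e (0.98) and Dnajc28 (0.75) rose and passed in each refit without 1 library. Ifnar1 (0.56, adjusted p = 0.00193), Jam2 (0.85) and Vps26c (0.77) rose with all libraries and lost the call without 5xFAD-Dp16 sham library 4 (0.0685, 0.152 and 0.578, the highest of their refits). App was higher by 0.71 (adjusted p = 0.0205) and Ifnar2 by 0.51 (adjusted p = 0.0319), and both lost the call without 5xFAD sham library 1, 2 or 3 or 5xFAD-Dp16 sham library 4 (highest adjusted p 0.358 and 0.552), Ifnar2 also without 5xFAD sham library 4.

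Outside the segment 14 genes passed the threshold with all libraries in the fit. The alarmin Il33 (0.97, adjusted p = 0.00998) and the myelin gene Mal (0.88, adjusted p = 0.0322) rose and Deaf1 fell by 0.57 (adjusted p = 0.011), with highest adjusted p of 0.8, 0.818 and 0.239 in refits without 1 library, each reached without 5xFAD-Dp16 sham library 4. All 3 also lost the call without 5xFAD sham library 2, and Mal without 5xFAD sham library 1 or 3. Without the 3 low libraries these 3, Mfge8 (adjusted p = 0.0839), St6galnac3 (0.055), Sox2ot (0.497), Sh3bp4 (0.501), Armh4 (0.78), Pax5 (0.982) and Chrnb3 (0.99) lost the call. Glra1 (-0.16) and the Y-linked Ddx3y (-0.57) turned in that fit, and 5xFAD-Dp16 sham library 4 was the only male of its group. The 14 are thus not shown to be an effect of the segment. The type I interferon list had a median of 0.66, with 40 of 40 members above 0, 0 past the threshold over all genes and 10 when adjusted over the list alone (camera adjusted p = 5.5e-14, and adjusted p = 0.176 with an estimated correlation). The 0 became 2 without 5xFAD-Dp16 sham library 1. The 10 became 1 without 5xFAD sham library 1 or 5xFAD-Dp16 sham library 2, 6 without 5xFAD sham library 4 and 3 without 5xFAD-Dp16 sham library 4. Per animal it was at 2.75 ± 0.24 against 2.01 ± 0.12 mean log2 CPM, an exact permutation p of 0.029 (two-sided), the smallest possible, and 0.067 without 5xFAD-Dp16 sham library 4 (n = 2 and 4), again the smallest possible. The groups held 2 females and 1 male (library 4) against 1 female and 3 males. These permutations therefore do not separate genotype from sex. Ifit1 (1.53, adjusted p = 0.0659) did not pass. The interferon-gamma list had a median of 0.52 with 0 higher and 5 when adjusted over the list alone (adjusted p = 0.285 with an estimated correlation), which became 0 without 5xFAD sham library 1 or 5xFAD-Dp16 sham library 4 and 1 without 5xFAD sham library 4. Its median was 0.22 without 5xFAD-Dp16 sham library 4, and 1 gene passed over all genes without 5xFAD-Dp16 sham library 1 or 2. Homeostatic (-0.49, adjusted p = 0.285) and plaque-associated microglia genes (-0.26, adjusted p = 0.577) were called lower by camera with the preset correlation and not with an estimated one, with Cst7 at -1.49 (adjusted p = 0.443) and Cd68 at -0.84 (adjusted p = 0.265). The homeostatic median was -0.27 without 5xFAD-Dp16 sham library 4 and the plaque-associated one -0.16 without 5xFAD sham library 2. When adjusted over the list alone 0 genes of either list passed, but 13 homeostatic and 6 plaque-associated genes did without 5xFAD sham library 4, 3 and 1 without 5xFAD-Dp16 sham library 1 and 11 and 1 without 5xFAD-Dp16 sham library 2. Myelin genes were higher by 0.76 (1 of 22, 19 when adjusted over the list alone) and thalamus genes by 1.36 (adjusted p = 0.285 and 0.577 with an estimated correlation), and without the 3 low libraries the medians were 0.14 and 0.05.

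Of 13 lists called here with the preset correlation, 0 were called with an estimated one. Fry called 1 list. The edgeR count of 47 genes (44 higher, 3 lower) was 1054 with no filter, 115 with DESeq2, 28 with the replicate number as a block, 27 without the 3 low libraries and 0 with the compared groups alone, and it was 26 and 28 without 5xFAD sham library 1 or 2 and 124, 183 and 19 without 5xFAD-Dp16 sham library 1, 2 or 4.

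The effect of 5xFAD on the Dp16 background was read between 5xFAD-Dp16 and Dp16 sham animals (n = 3 each). With all libraries in the fit it reached the threshold in no single gene. The edgeR test called 0 genes, with 1275 at an unadjusted p under 0.05, and DESeq2 called 11. The 4 named genes nearest to the threshold were Thy1 (log2 fold change 1.40), Ccl6 (2.16) and mt-Atp8 (-1.24), each with adjusted p = 0.0757, and Cst7 (5.22, adjusted p = 0.0819). The count was 1 without Dp16 sham library 2, 3 without 5xFAD-Dp16 sham library 4 and 511 with no filter. Without the 3 low libraries (n = 2 and 3) Thy1 (1.68, adjusted p = 8.17e-08) and Cst7 (5.71, adjusted p = 0.012) passed. The mt-Atp8 value draws on the same Dp16 sham animals that gave its rise against WT sham animals. As a set, type I interferon genes were higher (median 0.83, 0 of 40 over all genes, 16 when adjusted over the list alone, camera adjusted p = 0.0109 with an estimated correlation). Plaque-associated microglia genes had a median of 0.60 (0 of 30, 13 when adjusted over the list alone, adjusted p = 0.0735 with an estimated correlation; 0.37 and 0.0402 without the 3 low libraries) and complement genes 0.48 (adjusted p = 0.187 with an estimated correlation). Thalamus genes were higher by 1.37 and choroid plexus genes lower by -1.03 (both adjusted p = 0.593 with an estimated correlation), and without 5xFAD-Dp16 sham library 4 and the other low libraries the medians were -0.11 and -3.52. With 3 against 3 animals the smallest exact permutation p is 0.1, which the type I interferon list gave (0.96 log2 units per animal), and without 5xFAD-Dp16 sham library 4 its exact permutation p was 0.2 (two-sided, n = 2 and 3, smallest possible 0.1).

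Whether 5xFAD acted differently with and without the segment was tested as an interaction, which called 0 genes in edgeR (956 at an unadjusted p under 0.05) and 2 in DESeq2. Plaque-associated (-0.55), homeostatic (-0.43) and complement genes (-0.37) were called by camera with the preset correlation, each at adjusted p = 0.699 with an estimated correlation (medians of -0.45, -0.24 and -0.33 without the 3 low libraries). Of the 78 genes higher in 5xFAD than WT sham animals, 77 had the same sign between 5xFAD-Dp16 and Dp16, with a slope of 0.55, while over all 17518 genes the 2 sets of fold changes had a correlation of 0.02. These genes were chosen because they passed in the first comparison, which by itself lowers the slope. From sham to tofacitinib animals the slope was 0.81, 0.68 and 0.51 for 5xFAD, Dp16 and 5xFAD-Dp16 against WT. The 0.55 therefore does not show a weaker effect of 5xFAD with the segment. Of the 54 genes called between Dp16 and WT, 25 were also called in the same direction between 5xFAD-Dp16 and 5xFAD, against 0.11 for independent lists, and outside the segment 1 of 20 (correlation over all genes 0.07).

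In the tofacitinib groups the same genotype comparisons were made on other animals. Between Dp16 and WT 47 genes passed (45 higher, 2 lower), 37 of them in the segment, whose median was 0.56. Ifnar1 (0.63, SE 0.08, adjusted p = 1.44e-05), Ifnar2 (0.62), Dscam (0.76), Jam2 (0.74), Vps26c (0.76), the deubiquitinase Usp25 (0.67) and the synaptic phosphatase Synj1 (0.70) rose. Outside the segment Cbs fell by 0.59 (adjusted p = 0.00451), and the iodide transporter Slc5a5 (0.83), Prpf40b (0.43) and Lcat (0.56), the enzyme of cholesterol esters in lipoproteins, rose. All 11 passed in each refit without 1 library. Of the 54 genes called in sham animals, 33 were called in the same direction (0.11 by independence; correlation over all genes 0.26), 4 of them outside the segment. Type I interferon genes had a median of 0.23 (0.36 without Dp16 tofacitinib library 4) with 0 of 40 past the threshold either way, and interferon-gamma genes 0.28 (both adjusted p = 0.632 with an estimated correlation). The count was 214 with no filter, and it stayed within 36 to 46 without 1 library.

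Between 5xFAD and WT tofacitinib animals 56 genes passed (54 higher, 2 lower), 42 of which were also called in the same direction in sham animals, against 0.24 by independence (correlation over all genes 0.25). Cst7 (6.42, 22.2 ± 15.4 CPM, n = 5), Clec7a (4.59), Ccl6 (2.08), Cd68 (1.45), the peptide transporter Slc15a3 (2.07), the pattern receptor Tlr2 (1.92), AU020206 (2.02), Lgals3bp (1.32) and Thy1 (1.20) rose, and each passed in every refit without 1 library. Of plaque-associated microglia genes 12 of 30 rose, 21 when adjusted over the list alone (median 0.91, adjusted p = 0.000249 with an estimated correlation). Of complement genes 4 of 14 rose, 7 when adjusted over the list alone (1 fell on that measure; median 0.63, adjusted p = 0.00607 with an estimated correlation). Type I interferon genes had a median of 0.52 with 1 of 40 higher and 10 when adjusted over the list alone, interferon-gamma genes 0.48 with 0 and 6 (both adjusted p = 0.0718 with an estimated correlation), and homeostatic genes 0.45 with 2 of 16 and 8 (adjusted p = 0.109 with an estimated correlation). Over all genes 4 interferon-gamma genes passed without 5xFAD tofacitinib library 2, 2 without library 6 and 1 without WT tofacitinib library 3, and 2 type I genes without 5xFAD tofacitinib library 2 or 6. The homeostatic median was 0.29 without 5xFAD tofacitinib library 4. The list-alone count of 10 became 4 and that of 6 became 3 without 5xFAD tofacitinib library 1, and without library 2 the 6 became 10 and the 8 became 13. Thalamus genes were higher by 1.07 (adjusted p = 0.613 with an estimated correlation), a shift tied to 5xFAD tofacitinib library 2, since without the 3 low libraries the median was -0.33. Without the 3 low libraries the type I interferon (adjusted p = 0.00845), interferon-gamma (0.00521) and homeostatic lists (0.00845) were called with an estimated correlation. The count of 56 was 416 with no filter, 107 with 2 surrogate variables, 100 with DESeq2 and 0 with the compared groups alone. Without WT tofacitinib libraries 1 to 5 in turn it was 23, 14, 29, 23 and 23, and without 5xFAD tofacitinib library 1, 2, 4 or 5 it was 18, 85, 15 and 25. The plaque-associated count was 7 and 6 without WT tofacitinib library 1 or 2 and 6 without 5xFAD tofacitinib library 4. The complement count was 2 without WT tofacitinib library 3 and 0 without any other of these libraries but 5xFAD tofacitinib library 2, and the homeostatic count 5 without that library and 0 without each of the others.

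Between 5xFAD-Dp16 and WT tofacitinib animals 94 genes passed (92 higher, 2 lower), 38 in the segment, and 58 were shared with the sham comparison (0.75 by independence; correlation over all genes 0.33). Cst7 (6.06), Clec7a (4.33), Ccl6 (1.98), the NADPH oxidase subunit Cybb (2.52) and Tlr2 (1.90) rose, as did Lgals3bp (1.60, SE 0.23, 55.8 ± 4.4 against 18 ± 2.79 CPM, adjusted p = 0.000166), Ifit3 (1.39), the ubiquitin ligase Trim25 (0.81), Iigp1 (1.29), H2-K1 (0.86), H2-D1 (1.04), B2m (0.87), Ifnar1 (0.61), Ifnar2 (0.74), Il10rb (0.78), Tmem50b (0.66), the purine synthesis enzyme Gart (0.67) and Thy1 (1.42). These 18 passed in each refit without 1 library. Of type I interferon genes 6 of 40 rose, 25 when adjusted over the list alone (median 0.84), and of interferon-gamma genes 6 of 35, 17 when adjusted over the list alone (median 0.86). The 25 became 16 without WT tofacitinib library 5 and 15 without 5xFAD-Dp16 tofacitinib library 1. Of plaque-associated genes 9 of 30 rose, 16 when adjusted over the list alone (0.74), of complement genes 4 of 14, 8 when adjusted over the list alone (0.88), and of reactive astrocyte genes 3 of 28, 4 when adjusted over the list alone (0.32). These 5 lists were called with an estimated correlation (adjusted p = 0.000614 for type I interferon, plaque-associated and complement genes, 0.000785 and 0.0166 for the others). The count was 280 with no filter, 159 with 2 surrogate variables, 156 with DESeq2 and 52 with the compared groups alone, and within 63 to 94 without 1 library. The plaque-associated count was 3 without WT tofacitinib library 1 and 5, 5 and 4 without 5xFAD-Dp16 tofacitinib library 1, 2 or 3. The reactive astrocyte count was 1 without 5xFAD-Dp16 tofacitinib library 2 or 3, with a median of 0.20 without library 3. The complement count was 0 without either of these and 1 without any WT tofacitinib library or 5xFAD-Dp16 tofacitinib library 1.

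Tofacitinib itself was tested against sham within each genotype. The edgeR test called 0 genes in WT (491 at an unadjusted p under 0.05; DESeq2 1), 1 in Dp16 (347; DESeq2 2), 0 in 5xFAD (1017; DESeq2 1) and 0 in 5xFAD-Dp16 animals (1307; DESeq2 3). The gene in Dp16 animals was mt-Atp8, which fell by 1.25 (SE 0.21, 15.2 ± 4.31 against 36.1 ± 13.3 CPM, n = 5 and 3, adjusted p = 0.0199). Its adjusted p was 0.949 and 0.322 without Dp16 sham library 1 or 3 and 0.109, 0.131, 0.135 and 0.116 without Dp16 tofacitinib library 2, 3, 4 or 5, the highest of these refits being 0.949, and it was 0.555 with the replicate number as a block and 0.999 with the compared groups alone, where 0 genes passed in edgeR. The rise of mt-Atp8 against WT sham animals rests on the same 3 Dp16 sham animals. In the other groups mt-Atp8 had means of 15.1 to 17.3 CPM. Its fall is thus not shown to be the drug reversing a change of Dp16. In 5xFAD-Dp16 animals 4 genes passed without sham library 1 and 1 without sham library 2. Averaged over the 4 genotypes, 0 genes passed in edgeR (1354 at an unadjusted p under 0.05; DESeq2 1). The named genes with the smallest p were Rsrp1 (0.37), Bcas2 (0.20), Cox17 (0.29) and Lrrn1 (-0.20), each with adjusted p = 0.618. Ifnar1 was at 0.03 and the cytokine receptor Il2rb at -1.44 (adjusted p = 0.618). Il2rb had group means of 0.0652 to 0.641 CPM, a level left to counting error. Its mean was higher with the drug in WT animals (0.367 against 0.252 CPM) and lower in the other genotypes. A joint test of a difference in the effect between genotypes called 0 genes in edgeR (563 at an unadjusted p under 0.05; DESeq2 1). With no filter the counts were 46, 3, 394, 387, 91 and 582 for the 4 genotypes, their mean and the joint test.

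Interferon-stimulated genes were followed in the tofacitinib comparisons because the drug blocks the kinases downstream of interferon receptors. The type I interferon list had median log2 fold changes of -0.14 in Dp16, -0.37 in 5xFAD-Dp16 animals and -0.09 over the 4 genotypes, with 0 of 40 members lower over all genes in each and 1 in 5xFAD-Dp16 when adjusted over the list alone. Camera called these with the preset correlation but not with an estimated correlation (adjusted p = 0.977, 0.737 and 1.0). Per animal the list was 2.33 ± 0.18 in treated and 2.75 ± 0.24 mean log2 CPM in sham 5xFAD-Dp16 animals (n = 4 and 3, exact permutation p = 0.086, two-sided, smallest possible 0.029). The differences in WT (0.15, p = 0.35), Dp16 (-0.09, p = 0.66) and 5xFAD animals (-0.1, p = 0.59) had exact permutation p as given, and the mean over genotypes was -0.12 (permutation p = 0.23). In 5xFAD-Dp16 animals Ifit2 (-0.63), Irf7 (-0.83) and Ifit1 (-0.77) did not pass, each at adjusted p = 0.668. Without the 3 low libraries the list's median there was -0.16 (adjusted p = 0.825 with an estimated correlation). That fit keeps 5xFAD-Dp16 tofacitinib library 1, whose thalamus (5.0) and striatum lists (4.64) were the highest of the 31 libraries left. Plaque-associated microglia genes differed by 0.05 per animal over the genotypes (permutation p = 0.6).

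Ribosomal protein genes were called higher over the 4 genotypes by camera with the preset correlation (median 0.17, 0 of 34 over all genes, 29 when adjusted over the list alone, adjusted p = 0.757 with an estimated correlation). JAK-STAT transducers (-0.1, adjusted p = 0.757), interferon-gamma (-0.09, adjusted p = 1.0), striatum (0.73, adjusted p = 1.0) and glucocorticoid-responsive genes (0.1, adjusted p = 1.0) were called in the same way. In 5xFAD animals myelin (0.51), thalamus (1.41) and striatum genes (1.67) were called higher and excitatory neuron genes (-0.27) lower, and in 5xFAD-Dp16 animals myelin genes lower (-0.53) and ribosomal protein (0.3) and glucocorticoid-responsive genes (0.3) higher. With an estimated correlation these had adjusted p of 0.827 in 5xFAD and 0.737 in 5xFAD-Dp16 animals. Without the 3 low libraries, 5xFAD tofacitinib library 2 among them, the medians in 5xFAD animals were 0.29 for myelin, 0.10 for thalamus, -0.10 for striatum and -0.12 for excitatory neuron genes. Those in 5xFAD-Dp16 animals were 0.07 for myelin, 0.29 for ribosomal protein and 0.05 for glucocorticoid-responsive genes, and the striatum median over the 4 genotypes was 0.20. In WT animals 4 lists and in Dp16 animals 8 lists were called with the preset correlation, and 0 in any tofacitinib comparison with an estimated one.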

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

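The tests of explanations in this part were chosen after the patterns were seen. In each group of 4 or 5 animals the highest and lowest values of 18 measures were compared with the others of the group, and 9 of 108 such comparisons held a value far from the rest, where chance sets apart about 1 in 20. The gene model Gm42418 was not among the measures. It took 2.424% of the counts in WT sham library 5 and 0.257 to 0.413% in the other WT sham libraries. The next highest share was 1.006%, in WT tofacitinib library 4.

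The mean of hippocampal neuron markers was far below the other animals of the group in WT tofacitinib library 3 (4.52, others 5.41 to 5.68 log2 CPM) and 5xFAD tofacitinib library 2 (4.17, others 5.35 to 5.79), and lower in 5xFAD sham library 3 (5.47, others 5.64 to 5.67). In WT tofacitinib library 3 the astrocyte gene Gfap (133 CPM, others 454 to 557) and the interferon receptor subunit Ifngr2 (44.6 CPM, others 70.2 to 75.8) were below the rest and Cst7 above it (0.823 CPM, others 0.0501 to 0.247). App was above the rest in 5xFAD tofacitinib library 2 (2150 CPM, others 1350 to 1560), and Thy1 below it in Dp16 tofacitinib library 1 (782 CPM, others 890 to 934). Cst7 was above the rest in WT sham library 4 (0.383 CPM, others 0 to 0.0626).

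WT tofacitinib library 3, 5xFAD tofacitinib library 2 and 5xFAD-Dp16 sham library 4 were low in hippocampal markers. A first test of sequencing depth by library totals set apart WT tofacitinib library 3 alone (14.9 M counts, the lowest). The 5xFAD and 5xFAD-Dp16 libraries held 16.7 and 16.9 M counts. By comparison, 5xFAD-Dp16 sham library 2, with 15.8 M, was at 5.75 in hippocampal markers. A second test was then chosen on the ground that fewer reads raise no list of genes. In each of the 3 a list of another region exceeded all 31 libraries that were not low by 0.66 log2 units or more. That measure was already known and also serves for RNA of another region, so it does not by itself decide on depth. RNA of another brain region may be the source, since in 3 of the 3 libraries a neocortex, striatum or thalamus and habenula list lay above all 31 libraries that were not low. These lists stood at 5.93 (striatum) in the WT library, 6.73 (thalamus) in the 5xFAD library and 5.66 (thalamus) in the 5xFAD-Dp16 library, against 4.64 and 5.0 in the highest of the 31, and set against all libraries the 5xFAD-Dp16 library was highest in none. No biological explanation was tested.

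Type I interferon-stimulated genes were higher in 5xFAD-Dp16 than WT sham animals by a median of 1.54. Without the 3 libraries low in hippocampal markers the median was 1.3 with an adjusted p of 0.000205 from camera with an estimated correlation (8.9e-05 with all libraries, and 1.8e-60 to 7.8e-51 over the other settings with the preset), which argues against these libraries as the whole source. More microglia of an unchanged state would raise homeostatic microglia genes alike, but their median was 0.17 (quartiles -0.01 and 0.3; 0.33 without 5xFAD-Dp16 sham library 4, which had their lowest level, 0.06 without library 1 and -0.02 without library 2), below the interferon list's lower quartile of 0.85, which argues against this as the whole source and leaves a part open. Reads shared between paralogs such as the Ifit and Oas genes were not tested. A joint effect of the segment and the 5xFAD transgenes may contribute and stays a hypothesis: the interaction called 0 genes in edgeR (956 at an unadjusted p under 0.05, DESeq2 2), and the list's interaction median was 0.15 (adjusted p = 0.312, and 0.037 with the replicate number as a block to 1.0 without the 3 libraries).

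Type I interferon-stimulated genes had a median of -0.37 with tofacitinib in 5xFAD-Dp16 animals (adjusted p = 0.737 with an estimated correlation). Without 5xFAD-Dp16 sham library 4 and the other libraries low in hippocampal markers the median was -0.16, so that library may account for part of it. The difference of the animal means moved less, from -0.42 to -0.39, which leaves the library's share open, and 5xFAD-Dp16 tofacitinib library 1, kept in that fit, also stood high in thalamus genes (5.0). The spread between animals may also account for it, as the exact permutation p of the animal means was 0.086 (two-sided, n = 4 and 3, smallest possible 0.029). An effect of JAK inhibition stays open and is not shown by these values.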

How the results depend on the processing

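The fit without the 3 libraries low in hippocampal markers and the permutation test of list levels were chosen after the data were seen. The median of the chromosome 16 segment held in every setting run (0.54 to 0.602 on the log2 scale). DESeq2 size factors in the edgeR fit left each count of genes within 1.5 times, and so did dropping the sex term, save for 1 gene in place of 0 between 5xFAD-Dp16 and Dp16 sham animals. For the named genes and the counts of called lists, 2046 values were unchanged under the settings chosen first. Another 257 were no longer past the threshold, 32 newly passed, 2 turned and 21 counts of lists moved. In the refits without 1 library these were 2719, 502, 5, 5 and 17. Unchanged means the same side of the threshold for a gene and within 1.5 times for a count of lists. It includes check genes that passed in neither fit, so it is not a measure of how many calls held. Totals of 14.9 to 21.1 M counts leave genes under about 1 CPM to counting error.

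With no filter on low counts, edgeR called 237 genes for Dp16 against WT sham, 245 for 5xFAD against WT, 1270 for 5xFAD-Dp16 against WT, 1054 for 5xFAD-Dp16 against 5xFAD, 511 for 5xFAD-Dp16 against Dp16 and 433 for the interaction. It called 214, 416 and 280 for Dp16, 5xFAD and 5xFAD-Dp16 against WT under tofacitinib. For tofacitinib against sham it called 46 in WT, 3 in Dp16, 394 in 5xFAD and 387 in 5xFAD-Dp16 animals, 91 for the mean and 582 for the joint test. Of the 1270 genes 1247 pass the filter, and the added genes changed the shared spread: the prior degrees of freedom became infinite, where they were 5.84 with the filter.

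With the libraries of the compared groups alone, which leaves fewer libraries to estimate the spread, the counts were 98 for Dp16, 14 for 5xFAD and 0 for 5xFAD-Dp16 against WT sham, 0 for 5xFAD-Dp16 against 5xFAD and 1 against Dp16. Under tofacitinib they were 0 for 5xFAD and 52 for 5xFAD-Dp16 against WT, and 0 for tofacitinib in Dp16. This setting does not exist for the mean over genotypes and the joint test, which use all libraries. Without the 3 low libraries the counts were 119, 85, 27 and 3 for Dp16 and 5xFAD-Dp16 against WT and 5xFAD-Dp16 against 5xFAD and Dp16 sham. No Dp16 or WT sham library is among the 3, so the 119 comes from the fit shared with the other groups. The cause of the other changes was not tested.

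DESeq2 called 94 and 348 genes for Dp16 and 5xFAD-Dp16 against WT sham, 115 and 11 for 5xFAD-Dp16 against 5xFAD and Dp16, 2 for the interaction, and 100 and 156 for 5xFAD and 5xFAD-Dp16 against WT under tofacitinib. For tofacitinib it called 1, 2, 1 and 3 in the 4 genotypes, 1 for the mean and 1 for the joint test. With 2 surrogate variables the counts were 129 for 5xFAD against WT sham, 2 for 5xFAD-Dp16 against Dp16, and 107 and 159 for 5xFAD and 5xFAD-Dp16 against WT under tofacitinib. With an estimated correlation 19 of 156 list calls in the comparisons and the interaction were kept, and 0 of the 7, 4 and 13 for differences of the drug's effect from that in WT. Fry called 1 list for 5xFAD-Dp16 against 5xFAD sham, where camera with an estimated correlation called 0, and 2 where it called 1 against Dp16 sham. Under tofacitinib fry called 4 where it called 2 for 5xFAD, and 6 where it called 5 for 5xFAD-Dp16, against WT. In the other comparisons the 2 tests called equal numbers of lists, 0 in each tofacitinib against sham comparison. The cause was not tested for any of these settings.

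With the replicate number as a replicate block the counts were 22 and 109 for 5xFAD and 5xFAD-Dp16 against WT sham, 28 for 5xFAD-Dp16 against 5xFAD and 0 for tofacitinib in Dp16, and no other count of genes left 1.5 times. Animals that share a number had a median correlation of -0.026 over 98 pairs, against 0.013 over 405 other pairs, and 2 of 34 libraries correlated best with a library of their own number, so the numbers were not used as pairs.

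Leaving out 1 library gave 23 to 46 genes for Dp16 against WT sham, 12 to 105 for 5xFAD against WT, 65 to 474 for 5xFAD-Dp16 against WT, 19 to 183 for 5xFAD-Dp16 against 5xFAD and 0 to 3 against Dp16. It gave 36 to 46, 14 to 85 and 63 to 94 for Dp16, 5xFAD and 5xFAD-Dp16 against WT under tofacitinib, 0 to 1 for tofacitinib in Dp16 and 0 to 4 in 5xFAD-Dp16 animals, and 0 for the interaction and the other tofacitinib tests.

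Between 5xFAD-Dp16 and WT sham animals, Th, Glra1 and Gata3 turned without the 3 low libraries (-0.52, -0.10 and -1.61). In the refits without 1 library their values ranged from -0.65 to 6.18, -0.18 to 9.02 and -1.55 to 8.16, the lowest without 5xFAD-Dp16 sham library 4. Glra1 turned between 5xFAD-Dp16 and 5xFAD (-0.16, and -0.26 to 10.12). The Y-linked Ddx3y turned between 5xFAD-Dp16 and 5xFAD without the sex term (-0.36), with 2 surrogate variables (-0.20) and without the 3 libraries (-0.57), and ranged from -0.52 to 0.86 in the refits without 1 library. In 5xFAD-Dp16 sham animals Ddx3y was at 82.3 CPM in library 4, the only male, and at 0 in libraries 1 and 2. Its fold change there thus rests on 1 animal, and the cause was not tested further.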

Other observations

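The tests of other splits in this part were chosen first, and the number drawn was raised to 100 after the results of fewer draws were seen. Outside the comparisons by genotype and drug, 11 genes differed between female and male animals over all 34 libraries. Xist, the RNA that silences the X chromosome, was higher in females (12.69 on the log2 scale), and the Y-linked Ddx3y (-12.37), Kdm5d (-10.86), Uty (-10.56) and Eif2s3y (-10.62) were lower. The X-linked genes Eif2s3x (0.54), Kdm6a (0.49), Kdm5c (0.39) and Ddx3x (0.35), which have partners on the Y chromosome, were higher in females.

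Choroid plexus genes varied within every group. Their mean per library ran from -0.41 to 4.57 log2 CPM in WT sham, 3.04 to 4.64 in Dp16 sham, -0.46 to 5.30 in 5xFAD sham and 0.82 to 4.56 in 5xFAD-Dp16 sham animals. Lymphocyte genes had medians of 0.31, 0.52 and 1.10 in Dp16, 5xFAD and 5xFAD-Dp16 against WT sham animals, with 0 of 9 past the threshold in edgeR and camera adjusted p of 0.503, 0.737 and 0.152. Feedback and target genes of JAK-STAT signalling had medians of 0.06, 0.13 and 0.15 (camera adjusted p = 0.966, 0.0545 and 0.282). Astrocyte (0.08, 0.06 and 0.05), endothelial (0.07, 0.06 and 0.22), blood (0.13, -0.07 and -0.14), monocyte and border macrophage (-0.10, -0.36 and 0.46) and oligodendrocyte precursor genes (0.05, 0.08 and 0.18) were not called by camera in these comparisons either. Between genotypes, the effect of tofacitinib on type I interferon genes differed from that in WT by -0.28 in Dp16, -0.22 in 5xFAD and -0.44 in 5xFAD-Dp16 animals, called with the preset correlation but not with an estimated one (adjusted p = 0.915, 0.98 and 0.743).

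For each comparison the libraries were regrouped into other splits of the same sizes and the edgeR test was run again. The real split alone gave as many genes for Dp16 against WT sham (54 genes, highest other split 0, 1 of 56 splits), 5xFAD against WT sham (78, highest other 37, 1 of 100), 5xFAD-Dp16 against WT sham (168, highest other 2, 1 of 56) and 5xFAD-Dp16 against 5xFAD sham (47, highest other 6, 1 of 35). The same held under tofacitinib for Dp16 (47, highest other 1) and 5xFAD against WT (56, highest other 9), each in 1 of 100 splits. For 5xFAD-Dp16 against WT under tofacitinib 2 of 100 splits, the real one included, gave as many as the real 94. The other called 206, over 2 times the real count, which points to a structure of the samples. Such counts were thus rare among regrouped libraries, with shares not adjusted over the comparisons. Where the groups differ in Dp16, the triplicated segment favours the real split. It held 34 of the 54, 41 of the 168 and 33 of the 47 genes in sham animals. Under tofacitinib it held 37 of the 47 and 38 of the 94. These counts do not exclude chance for the genes outside the segment. For 5xFAD-Dp16 against Dp16 sham the 10 possible splits are too few for a share under 0.05 (1275 genes at an unadjusted p under 0.05, highest other 1590, 6 of 10 as large).

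Counted at an unadjusted p under 0.05, since edgeR called 0 genes or 1, chance could not be excluded for the interaction (956 genes, highest other split 1518, 29 of 100 splits as large). Nor could it for tofacitinib in WT (491, highest other 1871, 52 of 100), Dp16 (347, highest other 646, 18 of 56), 5xFAD (1017, highest other 2808, 37 of 100) and 5xFAD-Dp16 animals (1307, highest other 4206, 20 of 35). The same was so for the mean over genotypes (1354, highest other 3124, 14 of 100) and the joint test (563, highest other 3709, 75 of 100). Splits with over 2 times the real count, in WT, 5xFAD and 5xFAD-Dp16 animals, the mean and the joint test, point to a structure of the samples other than the drug. In 5xFAD-Dp16 animals the split with 4206 genes set sham libraries 1 and 2 with tofacitinib libraries 2 and 4.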
